A study of Homo sapiens with 4 samples.

How the data were processed

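Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on 4 libraries from RKO cells, a human colon carcinoma line. An antibody raised against BRPF3 was used for 3 libraries and rabbit IgG for the other. Per the labels, BRPF3 was mapped in untreated asynchronous cells, in cells held for 22 h in 0.5 mM mimosine, and in mimosine-treated cells released for 3 h and exposed to 3 mM hydroxyurea (HU) for 1 h 30 min. The IgG library came from the last of these conditions. One description field of the BRPF3 libraries names other members of the BRPF family, while their titles and antibody field name BRPF3, and the antibody field was followed. Each condition had 1 BRPF3 library, so no value has a replicate and no test between conditions was made.

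Bowtie 0.12.8, SAMtools, MACS 1.4.0 and bedtools are named in the submitters' processing notes, without their order or settings. The authors deposited 1 peak list per BRPF3 library, and the names of all 3 lists give the IgG library as the control. Each list holds the position of a peak and a score, and the deposited score is the peak caller's p-value given as 10 times its negative base-10 logarithm, as read from the form of the lists and their lowest value of 50. The score is the authors' own value and was used in the report to rank, describe or filter peaks within a list. The submitters' processing notes name both hg18 and hg19. Peaks in 2 of the lists lie past the end of their chromosome in hg18 and in GRCh38, so positions are given as hg19, counted from 1. Reads, read depth and fragment lengths were not analysed here, so the depth behind each list is unknown.

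The score did not resolve the strongest peaks. Exactly 3100 was recorded for 903 asynchronous, 306 mimosine and 906 HU peaks, and 77, 30 and 68 peaks lay above that value. Peaks at 3100 had median widths of 6016, 5296 and 6289 bp, against 5013, 5025 and 5357 bp for those above it, so the order among peaks at or above 3100 is unresolved. The named regions and rank percentiles still followed the score as deposited, which puts peaks above 3100 first, except that values above 3100 were set to 3100 where shifts in rank between lists were counted.

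Peaks of different lists were called shared when they overlapped by at least 1 bp. Peaks of the 3 lists that overlapped were merged into regions, and each region was put in 1 of 7 classes by the lists that held a peak in it. Overlaps were set beside 1000 random placements of each peak on its own chromosome, between the first and last peak position of any list. Assembly gaps were not excluded from these placements, which makes the random overlap approximate. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Peak widths and scores were compared across lists in merged regions holding exactly 1 peak of each list. Peaks per Mb were counted on the 22 autosomes and chromosome X over the same span. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The overlap and chromosome calculations were tested on simulated data made from the 13160 asynchronous peaks. With peaks removed at random and the kept ones trimmed, 100% of kept peaks and 0% of removed peaks were found. Peaks of a list do not overlap each other, so this checks the code only. With peaks removed by score, 97.6% of an excess of removed peaks planted on chromosome X was recovered. This is a mean over repeated simulations, so it does not show how often a small excess would be found in a single data set. Matching on the mean rank in both lists and the comparison across chromosomes were not simulated.

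All 3 lists were called against the same IgG library, and without reads the effect of a shared control on the overlap could not be simulated. Regions named for their score were taken from the 5 of highest score per list and per class, with ties going to the wider region. This rule was set before the data were examined, but it did not fix which of the 5 are named. Within a class of several lists, regions were ordered by the lower of their within-list score ranks. The widest regions and those whose rank differed between lists were chosen after their values were seen.

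The reference used here holds a gene table for GRCh38 only, and positions were not converted between builds. The planned promoter share, genomic annotation, genes with a promoter peak, gene lists, peaks per gene and sequence composition of peaks were therefore not run. Alternatives planned before the data were examined were a score of 100 or more, equal numbers of top-scoring peaks, a reciprocal overlap of 50%, centres within 1 kb, merging of peaks within 1 kb, chromosomes 1 to 22 alone, and leaving out peaks wider than 10 kb. Circular shifts of whole lists, widths and distances at a score of 100 or more, and recovery by mimosine peaks with such a score were added after seeing the data. The comparison of widths in shared regions, the shares by score and the gaps of single-list peaks were also chosen after seeing the data.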

Results

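BRPF3 is a scaffold subunit of MYST-family histone acetyltransferase complexes, and the series set out to map it across the genome of synchronised RKO cells. RKO is an established colon carcinoma line. Mimosine, a plant amino acid, arrests cells around the start of DNA replication, and hydroxyurea (HU) depletes nucleotide pools and stalls replication. The lists covered asynchronous cells, cells in 0.5 mM mimosine for 22 h, and cells released from mimosine for 3 h and then given 3 mM HU for 1 h 30 min, called HU cells here. Each condition had 1 library and no replicate, so differences between lists describe these libraries and carry no p-value.

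BRPF3 peaks numbered 13160 in asynchronous, 11532 in mimosine and 13431 in HU cells. They covered 39.1, 24.5 and 43.6 Mb. The mimosine list was thus the shortest in both number and length. Its peaks had a median width of 1855 bp (interquartile range 1182 to 2693 bp), against 2644 bp (1820 to 3649 bp) in asynchronous and 2898 bp (1942 to 4037 bp) in HU cells. Peaks wider than 10 kb numbered 29 in mimosine cells, 114 in asynchronous cells and 153 in HU cells. The authors' score had a median of 277 in the mimosine list, 562 in the asynchronous list and 534 in the HU list. Scores below 100 were carried by 21.4%, 13.1% and 14.8% of peaks. The number of reads behind each list is unknown.

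Nearly all mimosine peaks touched a peak of the other lists. Of the 11532 mimosine peaks, 98.9% overlapped an asynchronous peak (95% interval 98.6 to 99.0%) and 99.5% an HU peak (99.4 to 99.6%), which left 132 and 54 peaks outside. In the other direction, 77.4% of asynchronous peaks (76.6 to 78.1%) and 75.4% of HU peaks (74.6 to 76.1%) overlapped a mimosine peak. Asynchronous and HU cells shared most sites, with 94.5% of asynchronous peaks (94.1 to 94.9%) found in HU cells and 91.2% of HU peaks (90.7 to 91.7%) found in asynchronous cells. Random placements gave a mean overlap of 2.27 to 3.36% for the 6 comparisons, and at most 3.90%. The shared base pairs made up 0.802 of the union for asynchronous and HU cells, 0.616 for asynchronous and mimosine cells, and 0.561 for mimosine and HU cells. All 3 lists were called against the same IgG library, which matches only the HU condition. With equal numbers of 5766 top-scoring peaks per list, 87.0% of asynchronous and 89.5% of HU peaks overlapped a mimosine peak, and 88.9% and 91.6% of mimosine peaks overlapped an asynchronous and an HU peak. At equal numbers, 89.98% of asynchronous peaks overlapped an HU peak. Lists of equal length give similar shares in both directions, so this setting cannot show whether the mimosine list is nested. In the full lists, 0 of the 5766 higher-scoring mimosine peaks lacked an asynchronous partner and 0 lacked an HU partner. Under a reciprocal overlap of 50%, 71.5% of mimosine peaks were found in asynchronous and 64.3% in HU cells, and 62.7% of asynchronous and 55.2% of HU peaks in mimosine cells.

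Merging gave 14039 BRPF3 regions, of which 10044 (71.5%, 95% interval 70.8 to 72.3%) held a peak in all 3 lists. A further 2060 regions (14.7%) were called in asynchronous and HU cells and not in mimosine cells. HU cells alone held 1134 regions (8.08%) and asynchronous cells alone 698 (4.97%). Mimosine cells alone held 34, mimosine and HU cells together 49, and asynchronous and mimosine cells together 20. These counts depended on the peaks used. At a score of 100 or more, 555 HU-only, 6 mimosine-only, 16 mimosine and HU and 4 asynchronous and mimosine regions were left. Regions in asynchronous and HU cells rose to 2291, while those in all 3 lists fell to 8530 and asynchronous-only ones to 469. With equal numbers of top-scoring peaks the order turned, with 239 HU-only, 380 asynchronous-only and 284 mimosine-only regions, beside 4804 in all 3 lists, 365 in asynchronous and HU, 350 in mimosine and HU and 198 in asynchronous and mimosine cells. The cut itself makes such regions, because a partner can lie below it. In the full lists, 0 of the 5766 higher-scoring mimosine peaks lacked an asynchronous partner and 0 lacked an HU partner. Likewise, 0 of the 6580 higher-scoring asynchronous peaks lacked an HU partner. In the main set, regions in all 3 lists had a median width of 3495 bp, those missing from mimosine cells 1776 bp, and those of a single list 1111 bp in HU, 966 bp in asynchronous and 410 bp in mimosine cells.

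**Figure D1:**
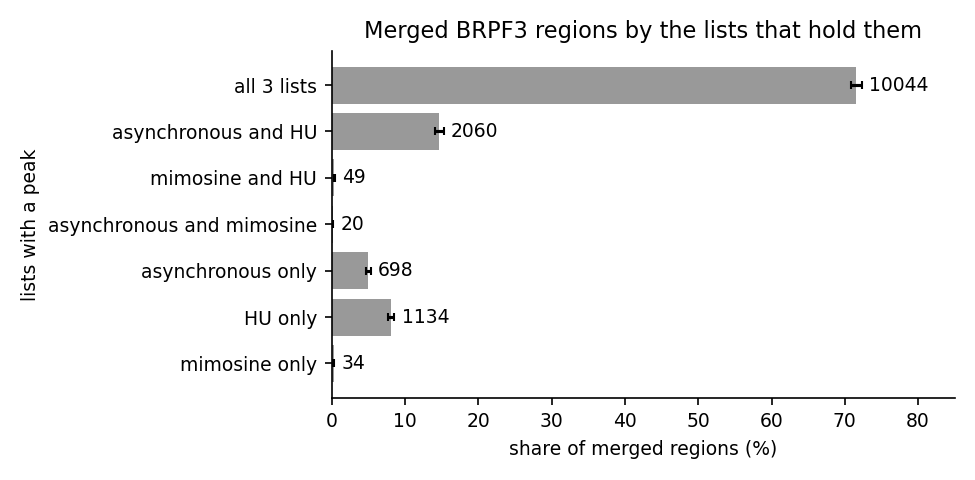
Bars show the share of the 14039 merged regions (%) in each combination of lists, with exact 95% intervals covering counting error only and the number of regions beside each bar. Regions in all 3 lists number 10044, and those in the asynchronous and HU lists number 2060.

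Peaks missing from mimosine cells lay mostly in the lower-scoring 50% of the asynchronous and HU lists, and not only at the lowest scores. Among the higher-scoring 50% of asynchronous peaks, 17 of 6580 (0.258%, 95% interval 0.151 to 0.413%) had no mimosine peak, against 2961 of 6580 (45.0%) among the lower-scoring 50%. For HU peaks the counts were 7 of 6716 (0.104%, 0.0419 to 0.215%) and 3302 of 6715 (49.2%). At a score of 100 or more, 1424 of 11438 asynchronous peaks (12.4%) and 1449 of 11446 HU peaks (12.7%) had no mimosine peak. At 200 or more, 482 of 9917 asynchronous peaks (4.86%) and 407 of 9901 HU peaks (4.11%) had none. With mimosine peaks limited to scores of 100 or more, an alternative added after seeing the data, the shares of the higher-scoring 50% without a partner were 1.66% and 1.25%. Recovery in mimosine cells rose from 8.36% in the lowest of 10 score groups of the asynchronous list to 95.7% in the fifth and 100% in the highest. Between asynchronous and HU cells, 0 of the 6580 higher-scoring asynchronous peaks and 1 of the 6716 higher-scoring HU peaks lacked a partner. Peaks called in a single list lay at a median rank percentile of 6.13 in the asynchronous, 4.93 in the mimosine and 6.92 in the HU list. The mimosine value rests on 34 peaks, and under a reciprocal overlap of 50% it was 19.5 on 3006 peaks. All but 34 of these 3006 overlapped a peak of another list by at least 1 bp. A peak narrower than 50% of its partner cannot pass that rule, and mimosine peaks were narrower at shared sites. How many failed for this reason was not counted. Peaks called in all 3 lists lay at 61.4, 50.7 and 62.5.

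**Figure D2:**
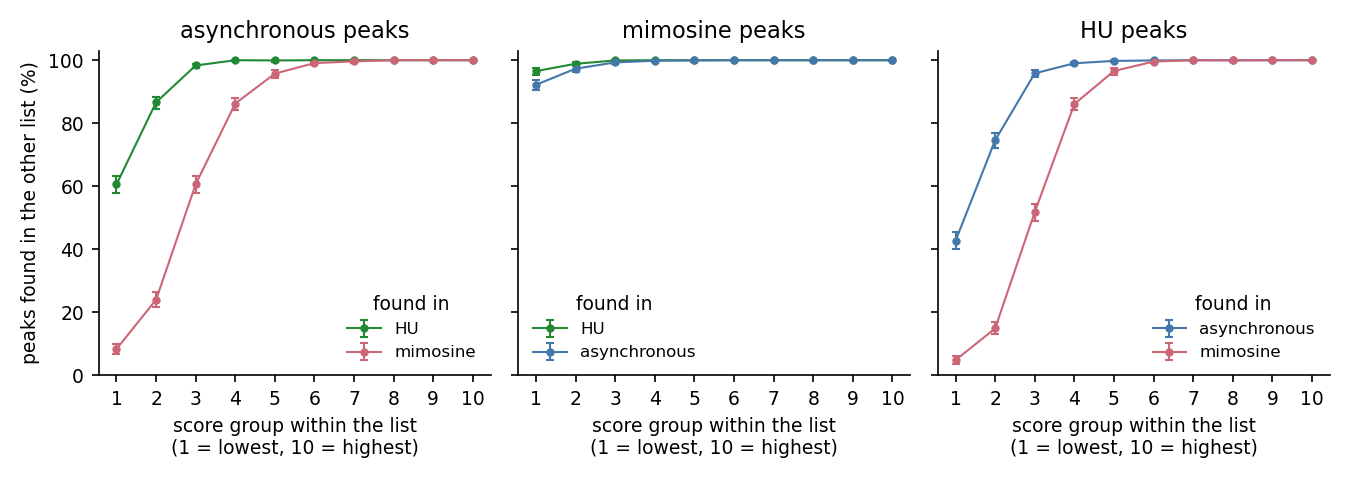
Points show the share of peaks of each list (%) that overlapped a peak of another list, in 10 equal groups by score within the list, with exact 95% intervals covering counting error only. Recovery of asynchronous peaks in mimosine cells runs from 8.36% in the lowest group to 100% in the highest.

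The 5 highest-scoring peaks of each list were held by the other lists as well. All of them scored above 3100, a range in which the score does not resolve the order, so they are examples of top-scoring peaks rather than a ranking. In asynchronous cells they included chr17:6914474-6919126 and chr9:123636558-123641009, both with the list's highest score. The region chr5:86415526-86424047 was also among the top 5 of asynchronous cells, and there the mimosine list held 4 peaks, the highest at rank percentile 68.7 of its list, and the HU list 1 peak at rank percentile 81.2. In mimosine cells the highest deposited score was at chr22:38898807-38903249, and in HU cells at chr6:33544032-33548664, which stood at rank percentile 85.5 in asynchronous and 86.3 in mimosine cells.

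Regions called in some conditions only were few at high scores. With a score of 500 or more, 31 of 7003 asynchronous and 15 of 6988 HU peaks had no mimosine peak. At that score, 0 of 7003 asynchronous, 0 of 3888 mimosine and 1 of 6988 HU peaks were found in neither other list. That HU peak was chr4:77702472-77705700, 3229 bp wide, with a score of 591 and rank percentile 52.9, and the next HU-only peak was chr3:67052727-67056273, with a score of 333. The leading asynchronous-only peak was chr4:151229980-151233058, with a score of 487 and rank percentile 45.9. It was followed by chrX:114985778-114997788, which spanned 12011 bp with a score of 236. Among regions shared by asynchronous and HU cells and absent from the mimosine list, chr2:20187572-20190615 led, at rank percentile 63.5 in asynchronous and 51.6 in HU cells. The leading region of mimosine and HU cells was chr3:48591223-48596020, where the mimosine peak covered 1523 bp and the HU peak 4798 bp. Mimosine-only peaks all scored 76.1 or less. The leading region of asynchronous and mimosine cells, chr2:91936629-91937335, scored 111 and 78.2.

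At shared sites the mimosine peaks were narrower. In the 8653 merged regions with exactly 1 peak per list (61.6% of all regions), the median width was 1981 bp in mimosine, 2906 bp in asynchronous and 3216 bp in HU cells. The mimosine peak was the narrower in 98.2% of regions against asynchronous cells (95% interval 97.9 to 98.4%) and in 99.9% against HU cells (99.85 to 99.97%). The median width ratio was 0.694 (interquartile range 0.571 to 0.802) against asynchronous cells and 0.630 (0.518 to 0.727) against HU cells. HU peaks were wider than asynchronous peaks in 75.1% of regions (74.1 to 76.0%), with a median ratio of 1.09. Peak centres lay a median of 159 bp apart between mimosine and asynchronous cells and 138 bp apart between HU and asynchronous cells. Of the 10044 regions in all 3 lists, 11.9% were split into 2 or more peaks in mimosine cells, 2.81% in asynchronous cells and 1.15% in HU cells. The order of scores was similar across these 8653 regions, with Spearman's rho of 0.935 for mimosine and HU cells, 0.921 for asynchronous and HU cells, and 0.897 for asynchronous and mimosine cells. These are correlations across regions, which are not independent replicates.

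**Figure D3:**
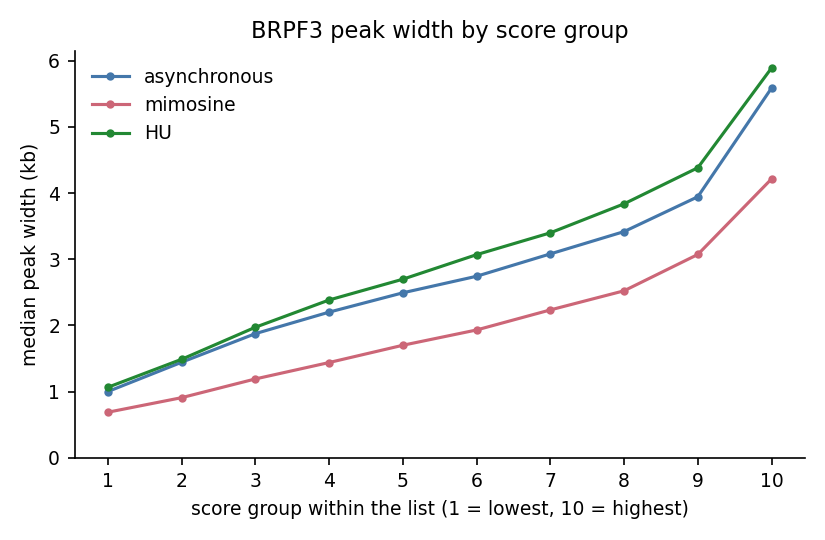
Points show the median peak width (kb) of each list in 10 equal groups by score within the list. Medians run from 689 to 4215 bp in mimosine, from 1001.5 to 5588 bp in asynchronous and from 1066 to 5891 bp in HU cells.

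Broad peaks were covered less completely by mimosine peaks than by those of the other condition, though more completely than the lists as a whole. The 114 asynchronous peaks wider than 10 kb were covered by mimosine peaks over a median of 76.6% of their length and by HU peaks over 98.7%. For the 153 HU peaks of that width the values were 71.4% by mimosine and 93.4% by asynchronous peaks. Over peaks of any width, the median covered by mimosine peaks was 63.3% for asynchronous and 56.7% for HU peaks. As pooled base pairs, mimosine peaks covered 72.3% of the wide asynchronous and 68.9% of the wide HU peaks, against 62.0% and 56.2% of the whole lists. The widest merged regions were chosen after their values were seen. The widest, chr7:130568466-130648968, was 80.5 kb long. Asynchronous cells held 2 peaks there, the larger 72.0 kb wide with a score of 1255 (rank percentile 75.4), and HU cells held 1 peak of 80.4 kb with a score of 74.5 (rank percentile 9.45). Mimosine cells held 2 peaks that covered 4.81% of the region. The next, chr9:21546407-21598685, was 52.3 kb long and was covered by a single HU peak, by 5 asynchronous peaks over 95.1% of its length and by 5 mimosine peaks over 56.0%. In the next 3 regions, on chromosomes 12, 10 and 2, mimosine peaks covered 74.9%, 82.3% and 82.6%.

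**Figure D4:**
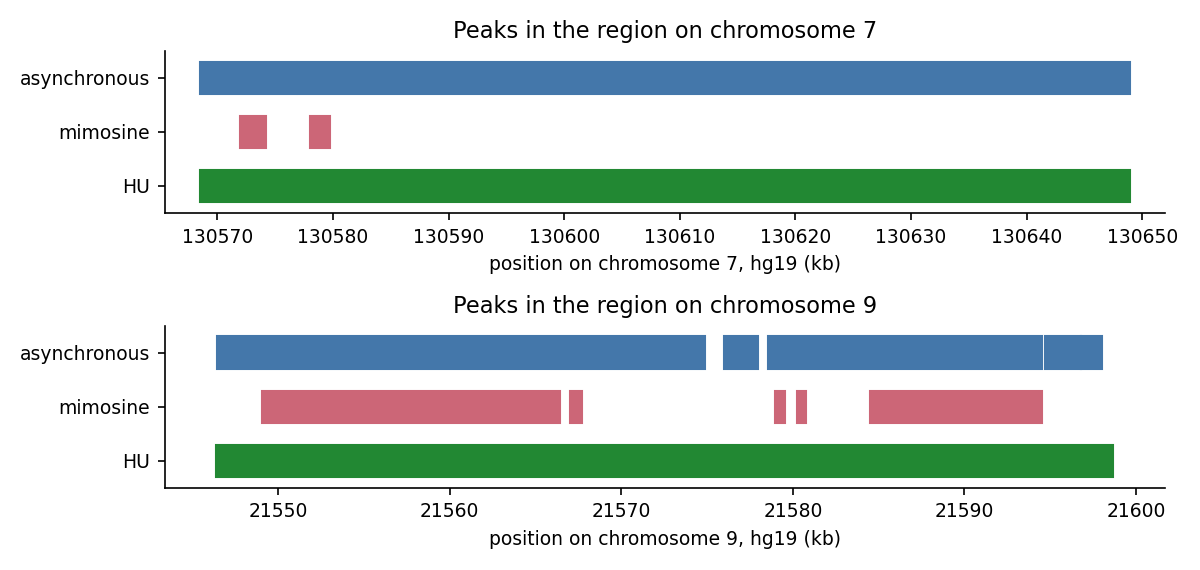
Blocks show the peaks of each list along the 2 widest merged regions, by hg19 position (kb), drawn to scale. In the chromosome 7 region the mimosine list covers 4.81% of the length, and in the chromosome 9 region 56.0%. Neighbouring asynchronous peaks lie too close together to be told apart at this scale in places.

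BRPF3 sites were unevenly spread over the genome. Chromosome 19 had the highest density, with 15.4 peaks per Mb in asynchronous, 12.6 in mimosine and 15.4 in HU cells, against 4.47, 3.92 and 4.56 over the autosomes and chromosome X. Chromosome 17 followed with 10.2, 8.88 and 10.1 peaks per Mb. Chromosomes 18, 13 and X had the lowest densities, and chromosome X held 2.49, 1.87 and 2.45 peaks per Mb. Of the 349 chromosome X regions called in asynchronous and HU cells, 110 (31.5%, 95% interval 26.7 to 36.7%) had no mimosine peak, against 1946 of 11744 (16.6%, 15.9 to 17.3%) on the autosomes. Chromosome X peaks also had lower scores, with a median of 291 in asynchronous and 295 in HU cells. Neighbouring peaks lay a median of 63.5, 65.7 and 62.1 kb apart in asynchronous, mimosine and HU cells, against 138, 158 and 136 kb under random placement. At a score of 100 or more, where no random placement was run, the medians were 75.5, 88.9 and 75.1 kb.

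**Figure D5:**
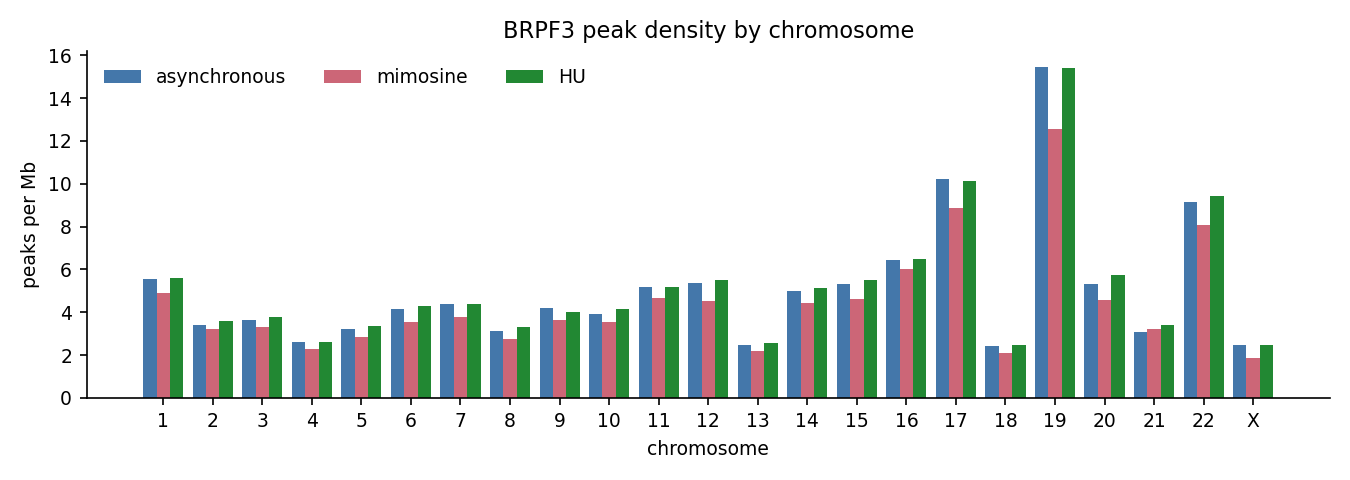
Bars show peaks per Mb on each autosome and chromosome X in the 3 lists. Chromosome 19 has 15.4, 12.6 and 15.4 peaks per Mb in asynchronous, mimosine and HU cells.

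Peaks of a single list lay closer to sites of the others than the same peaks placed at random. The 698 asynchronous-only peaks had a median gap of 18.5 kb to the nearest peak of another list, and 29.1% lay within 5 kb. The same peaks placed at random gave 134 kb and 7.31%. The 1134 HU-only peaks had a median gap of 15.6 kb and 32.8% lay within 5 kb, against 127 kb and 6.35% at random. The 34 mimosine-only peaks had a median gap of 35.8 kb and 8 of them (23.5%) lay within 5 kb, against 152 kb and 8.82% at random. No spread over repeated placements is given for these random values, and the mimosine contrast rests on few peaks.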

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

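Circular shifts, widths and distances at a score of 100 or more, and recovery by mimosine peaks of that score were chosen only after the results were seen; the other alternatives were planned. The width ratios and the shares of higher-scoring peaks were themselves chosen after the data were seen. On chromosomes 1 to 22 alone, all 6 overlaps stayed inside the exact 95% intervals of their main values, the largest change being asynchronous in mimosine at 77.8%. Numbers of peaks, covered length without peaks wider than 10 kb, and regions per class with peaks within 1 kb merged stayed within 1.5 times their main values. Pairwise overlaps are given in the order asynchronous in mimosine, asynchronous in HU, mimosine in asynchronous, mimosine in HU, HU in asynchronous and HU in mimosine. With a score of 100 or more, they became 75.2%, 95.9%, 99.7%, 99.9%, 95.01% and 74.8%, the last inside its main interval. With equal numbers of top peaks they were 87.0%, 89.98%, 88.9%, 91.6%, 89.8% and 89.5%. A reciprocal overlap of 50% gave 62.7%, 91.0%, 71.5%, 64.3%, 89.2% and 55.2%, which put mimosine peaks less often in HU than in asynchronous cells, and centres within 1 kb gave 75.5%, 90.9%, 89.3%, 88.3%, 88.9% and 73.1%. A score of 100 or more left 555 HU-only, 6 mimosine-only, 16 mimosine and HU, and 4 asynchronous and mimosine regions. Regions in asynchronous and HU cells rose to 2291 and those in all 3 lists fell to 8530, both within 1.5 times their main values. Equal numbers gave 4804 regions in all 3 lists, 365 in asynchronous and HU, 350 in mimosine and HU, 198 in asynchronous and mimosine, 380 asynchronous-only, 239 HU-only and 284 mimosine-only. Asynchronous-only and mimosine-only regions thus outnumbered HU-only ones, against the main order. By construction, equal numbers use fewer peaks, and a region can count as single-list because its partner fell below the cut. Under a reciprocal overlap of 50%, median rank percentiles of peaks called in 1, 2 and 3 lists were 6.82, 26.6 and 65.9 in asynchronous, 19.5, 39.7 and 64.5 in mimosine, and 8.06, 30.6 and 68.6 in HU cells. All but 34 of the 3006 mimosine peaks called in 1 list under this rule overlapped another list's peak by at least 1 bp. The cause of the other shifts was not tested. With mimosine peaks scoring 100 or more, 1.66% of the higher-scoring 50% of asynchronous peaks and 1.25% of those of HU cells lacked a partner. At a score of 100 or more, the median width ratio of mimosine peaks was 0.711 to asynchronous and 0.643 to HU peaks. Alternatives that need promoters, genes or sequence were not run, because no annotation or genome of the files' build was used. Read depth is unknown and limits what an absent peak means. No paired analysis was possible because each group has 1 library.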

Other observations

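All tests in this part were chosen only after the results were seen. Among the 8653 regions with 1 peak per list, score ranks were recomputed within this same set for each list, and a region was counted where its rank in 1 list differed by at least 20 percentile points, in the same direction, from both others. Asynchronous cells stood apart in 353 regions (4.08%; 163 higher, 190 lower), mimosine cells in 244 (2.82%; 111 higher, 133 lower) and HU cells in 100 (1.16%; 63 higher, 37 lower). The regions named here were chosen after their values were seen. Lower in mimosine cells was chr11:62603815-62610071, at rank percentile 23.1 against 85.5 in asynchronous and 80.1 in HU cells, and higher was chr11:566749-570058, at 67.5 against 2.19 and 29.4. Higher in HU cells was chr13:45693416-45696445, at 65.7 against 13.1 in asynchronous and 8.97 in mimosine cells, and lower was chr14:24607918-24611983, at 18.8 against 63.8 and 53.5. Lower in asynchronous cells was chr1:151961386-151967111, at 20.9 against 80.7 in mimosine and 87.2 in HU cells, and higher was chr7:97498607-97502388, at 56.3 against 1.22 and 7.18. No replicate shows how often ranks move this far between libraries of the same condition.

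The mimosine list was shorter and nearly nested in the others. Loss of a set of strong sites under mimosine would leave higher-scoring HU peaks without a partner. Of the higher-scoring 50% of HU peaks, 0.104% lacked one, below the 1% set after the data were seen. That argues against outright loss of many such sites and not against weaker peaks there. With mimosine peaks limited to scores of 100 or more, 1.25% lacked one, which is above that bound and decides nothing here. Weaker signal or lower depth in the mimosine library predicts that the missing peaks lie at low scores. Of the higher-scoring 50% of asynchronous peaks, 0.258% lacked a partner, below the 1% set for it after the data were seen. With mimosine peaks scoring 100 or more, 1.66% did so. The bound was set for mimosine peaks of any score, and this limit removes the low-scoring partners that a weaker library would hold. The 1.66% therefore decides nothing about this explanation. A uniform reduction of BRPF3 binding under mimosine may give the same values. Depth, the control that matches only HU cells, and culture state are not separated with 1 library per condition, so this stays open.

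Mimosine peaks were narrower than those of the other lists. Lower scores alone would give equal widths at equal scores. Over 20 bins of scores below 3100, however, the median ratio of mimosine width was 0.880 to asynchronous and 0.791 to HU width. The ratio was below 1 in all 20 bins for both, which argues against lower scores as the whole cause. A fixed difference in how far the caller extends peaks may account for the gap to asynchronous cells at equal scores below 3100. A shorter fragment length in the mimosine library could give such a difference. The gap below 3100 was 210 to 356 bp in every bin. Its slope on asynchronous width was 0.008 bp per bp (95% of 1000 resamplings of peaks between −0.017 and 0.033). Peaks at 3100 or more were left out of the bins. At exactly 3100, median widths were 6016 bp in asynchronous and 5296 bp in mimosine cells, a larger gap than in any bin. The slope therefore says nothing about peaks at or above 3100. At shared sites, where scores were not matched, median widths were 1981 bp in mimosine and 2906 bp in asynchronous cells. An offset of 210 to 356 bp would cover only part of that difference. A fixed difference does not account for the whole gap to HU cells at equal scores below 3100. That gap ranged from 319 to 817 bp with a slope on HU width of 0.121 (0.0994 to 0.144). However, HU minus asynchronous width had a slope of its own of 0.128 (0.105 to 0.154), so a fixed mimosine offset as part of the gap to HU cells stays open. Scores depend on depth, so equal scores need not mean equal enrichment, and a biological difference in width stays open for both gaps.

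Regions called in asynchronous and HU cells were missing from the mimosine list more often on chromosome X. Matched on asynchronous score, 118 peaks were missing against 102.9 expected, a count 4 of 1000 shuffles reached; matched on HU score, 116 were missing against 100.3, which 1 of 1000 reached. Matched on the mean rank in both lists, 110 regions were missing, 13.3 more than expected, and 12 of 1000 shuffles reached that on chromosome X. Chromosome X was singled out after the values of 23 chromosomes were seen, and 198 of 1000 shuffles had some chromosome standing as high, while chromosome 5 stood higher in these data. Most of the excess over the autosomal share of 57.8 regions went with lower scores, and the remainder may be chance, so these data do not decide whether lower scores alone account for the pattern, and no biological explanation was tested.

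A search of 1268 windows of 2 Mb for clusters of missing peaks found no clear case. Windows were compared by the number missing above expectation, so a window with few peaks could hardly stand out. The highest excess for asynchronous peaks was chr6:26000001-28000000, with 31 of 69 missing against 25.1 expected, and 66 of 1000 shuffles had a window as high. For HU peaks it was chr19:36000001-38000000, which 605 of 1000 shuffles matched.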
